A study of Mus musculus with 4 samples.

How the data were processed

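Each of the 4 samples was hybridised to its own biotin-labelled Affymetrix mouse array, per the labels' protocols. The deposited values are log2 RMA values, RMA being named in the submitters' processing notes, without a version. RMA corrects the background, quantile normalizes the probes between arrays and summarises them per probe set on the log2 scale. The chip definition was not given in the sources used here. Quantile normalization forces the arrays to share a distribution, so a change in total RNA per cell would not be seen. The table held 45101 probe sets. No further normalization was applied, and 0 columns of other samples were present.

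The 64 control probe sets (AFFX) were left out of the tests and used only for the signal ratio of the 3' to the 5' end. Gene names came from the platform annotation, of which 34945 of the 45037 remaining probe sets carried a single gene, 932 several genes and 9160 were not listed, and no gene was named from a probe set with several. The gene identifiers of 34741 single-gene probe sets were found in the RefSeq gene table of assembly GRCm38, which supplied current symbols, and 204 were not. No genome build is named for the array, so no coordinates are given. Probe sets at or above the 40th percentile of the mean log2 value over the 4 arrays (4.17) were kept, which left 27022. A gene was represented by its kept probe set with the highest mean, and where another kept probe set of a named gene had the opposite sign its value is given.

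Induced arrays were compared with control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over the 27022 probe sets). There were 2 residual degrees of freedom, a prior standard deviation of 0.115 and 3.82 prior degrees of freedom, and the median standard deviation between replicates was 0.109. Differences are induced minus control means of log2 values with the standard error of the model, and folds are 2 to the power of that difference. Since each group holds 2 arrays, p-values rest largely on the spread pooled across probe sets.

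The tests, the filter, 27 gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. A list needed at least 3 kept members, which left 26. It was tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. The sex-linked list was described and not tested. The named genes are the 10 in each direction with the largest moderated statistic among separated genes, used because fewer than 5 genes passed the threshold in either direction, up to 4 members per list with the largest absolute statistic, and 15 genes fixed by name; genes named only by a clone or predicted identifier were skipped. The alternatives were no filter and a filter at the 60th percentile, a second quantile normalization, centring on array medians, eBayes with trend and robust, the mean of a gene's probe sets, other thresholds, the replicate number as a block, and leaving out each array in turn. With an array left out 1 residual degree of freedom remained, and the lone array of its group was assumed to vary like the other group. A planned test of miR-203 seed matches in 3' untranslated regions was not run, since no such sequences were used here.

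The labels give both groups replicate numbers 1 and 2 without saying that a number marks a litter, so the main fit had no block.

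The tests were checked on 20 simulated data sets of 27022 probe sets, in which 200 were changed. The means were the real ones. Each standard deviation was drawn from the fitted prior, whatever the probe set's own spread or mean level, so the rates need not hold for the real arrays. The test recovered 0.94% of probe sets changed 1.5-fold, 49.7% of those changed 2-fold and 95.6% of those changed 4-fold, with 4.4 false calls on average. A planted list of 27 probe sets shifted by -0.5 was called in 20 of 20 simulations and 0 of 400 unshifted lists were, with independent noise between probe sets, which real arrays do not have.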

Results

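The series measured messenger RNA in sorted skin cells of mouse pups in which the microRNA miR-203 had been switched on. miR-203 is abundant in the differentiating layers of the epidermis and scarce in the basal layer, where the dividing cells lie. The induced animals carried a doxycycline-responsive miR-203 transgene, a keratin 14 promoter driving the doxycycline-dependent activator (rtTA), and a keratin 14 promoter driving a nuclear green fluorescent protein (H2BGFP). Their control littermates, labelled wild type, lacked the activator, so that the miR-203 transgene had no driver. The groups therefore differed in the activator as well as in miR-203, and effects of these cannot be told apart here. Cells were sorted at postnatal day 4, 24 h after doxycycline, with a gate that is not given in the sources used here, and each RNA was hybridised to its own Affymetrix array. There were 2 control and 2 induced arrays, labelled as biological replicates, and their small number limits the precision of every value. The comparison asks which transcripts differ within a day of miR-203 induction. The probe sets analysed do not measure the mature microRNA, so the induction itself was not checked here.

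The 4 arrays had medians of 4.74 and 4.79 (controls) and 4.78 and 4.76 (induced) on the log2 scale of the deposited values, which ran from 2.09 to 14.6. Across the 27022 probe sets kept, which stood for 13489 named genes, Pearson's r between replicates was 0.995 for the controls and 0.994 for the induced arrays, against 0.991 to 0.993 between groups. The mean within-group r exceeded the mean between-group r by 0.00206. The first principal component held 47.9% of the variance and placed both controls (-22.4 and -10.4) apart from both induced arrays (21.6 and 11.3). The next held 29.9% and parted the induced arrays from each other (14.7 and -21.9). Signal from the 3' end exceeded that from the 5' end of the actin control transcript by 1.05 and 1.15 in the controls and 1.16 and 1.14 in the induced arrays, and for Gapdh by -0.09, -0.00, -0.05 and -0.05.

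Induced replicate 1 differed from the other 3 arrays in sex-linked transcripts. Xist, the non-coding RNA of the inactive X chromosome, had a log2 value of 5.86 there against 10.6 and 10.8 in the controls and 11.2 in induced replicate 2. Eif2s3y, a gene of the Y chromosome, had a value of 9.38 there against 2.82, 2.52 and 2.72. The groups therefore overlapped for both genes, with adjusted p = 0.722 for Xist and 0.639 for Eif2s3y.

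At the level of single genes, 0 probe sets and 0 genes had an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.158. At an unadjusted p under 0.05 there were 2728 probe sets (1461 higher and 1267 lower in the induced arrays), where chance gives 1351, and 1298 genes (593 higher and 705 lower). With a variance prior that follows the mean level and is robust to outlying variances, the same test called 126 probe sets (68 higher, 58 lower) and 81 genes (54 higher, 27 lower). Both induced arrays lay on the same side of both controls, with a mean difference of at least 1.5-fold, for 236 genes, 135 of them higher and 101 lower. The other 2 ways of pairing the 4 arrays gave 36 and 22 such genes, and there were 362 without control replicate 2 and 364 without induced replicate 2, when a single array stood for its group. Of all 13489 genes, 39.4% were separated in this way at any size, where chance gives 33.3%. Among the separated genes, the 10 with the highest test statistic in each direction are named here, none of them past the threshold. Those higher in the induced arrays were Rhpn2 (difference in mean log2 value 1.44 ± 0.14 SE, n = 2 and 2), Tchhl1 (1.35 ± 0.16), Krtap28-13 (1.21 ± 0.13), Lrrc15 (1.21 ± 0.13), Sptssb (1.19 ± 0.12), Krtap4-16 (1.12 ± 0.13), Procr (1.08 ± 0.11), Ly6g6d (1.08 ± 0.12), Krtap5-2 (1.06 ± 0.12) and Krtap5-5 (1.06 ± 0.13), each with an adjusted p of 0.158. Procr is the endothelial protein C receptor, and the Krtap genes encode keratin-associated proteins of the hair shaft. Those lower were Slc18b1 (-1.61 ± 0.18), Pola1 (-1.19 ± 0.11), Atf2 (-1.09 ± 0.13), Ncapg2 (1.99-fold lower), Sh3bgrl (-0.96 ± 0.13), Naa50 (-0.95 ± 0.12), Zc3hav1l (-0.89 ± 0.09), Cav1 (-0.84 ± 0.10), Adk (-0.83 ± 0.10) and Ahcy (-0.75 ± 0.10), with adjusted p values of 0.158 or, for Sh3bgrl, 0.163. Ncapg2 encodes a condensin II subunit, and Adk and Ahcy encode adenosine kinase and S-adenosylhomocysteine hydrolase. The control values of Rhpn2 (4.02 and 3.98) and the induced mean of Slc18b1 (4.15) lay below the filter level of 4.17, so the sizes of both differences are at best lower bounds and no fold is given. For Atf2, 1 of its 3 other kept probe sets had the opposite sign (0.07 ± 0.14), at a dimmer control mean of 4.94 against 7.86.

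Genes of DNA replication and the G1/S transition were lower as a group in the induced arrays. All 27 measured members had a lower mean there, 26 of them in both induced arrays against both controls, with a median difference of -0.48 (1.39-fold lower). Pola1, the catalytic subunit of DNA polymerase alpha, had a log2 value of 7.88 ± 0.16 (SD, n = 2) in controls and 6.69 ± 0.01 in induced arrays, which is 2.29-fold lower. Cdc45 and Mcm3, parts of the replicative helicase, differed by -0.75 ± 0.17 (SE) and -0.73 ± 0.16, and the licensing factor Cdt1 by -0.57 ± 0.15. The only other kept probe set of Cdc45 had the opposite sign (0.16 ± 0.10), at a dimmer control mean of 4.85 against 6.69. Of the 27 members, 0 passed over all genes and 18 were lower when adjusted over the list alone. The list passed limma's camera test with its preset correlation of 0.01 (adjusted p = 2.03e-16), but not with an estimated correlation of 0.76 (adjusted p = 0.682). The median was -0.31 without induced replicate 1, the array with Y-linked transcripts, and the list stayed past the threshold in camera without each array in turn, in fits with a lone array in a group and the spread taken from the other group.

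Mitosis genes were also lower as a group. Of 24 measured members 23 had a lower mean in the induced arrays, 11 of them separated, with a median difference of -0.21. Bub1, a spindle checkpoint kinase, differed by -0.48 ± 0.14, the spindle midzone protein Prc1 by -0.36 ± 0.11, Cdk1 by -0.33 ± 0.13 and the proliferation marker Mki67 by -0.12 ± 0.18. None of the 24 passed when adjusted over the list alone. The list passed camera (adjusted p = 1.75e-05; adjusted p = 0.822 with an estimated correlation). Without induced replicate 1 the median was -0.05 and the adjusted p 0.215, so that this array decided the call, and without induced replicate 2 the median was -0.36. The cyclin gene Ccnd1 differed by -0.19 ± 0.17 and Myc by 0.08 ± 0.11 on the same scale, and the list of CDK inhibitors and p53 response genes had a median of 0.05 and did not pass (adjusted p = 0.615), with Cdkn1a, the p21 gene, at 0.10 ± 0.11.

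**Figure D1:**
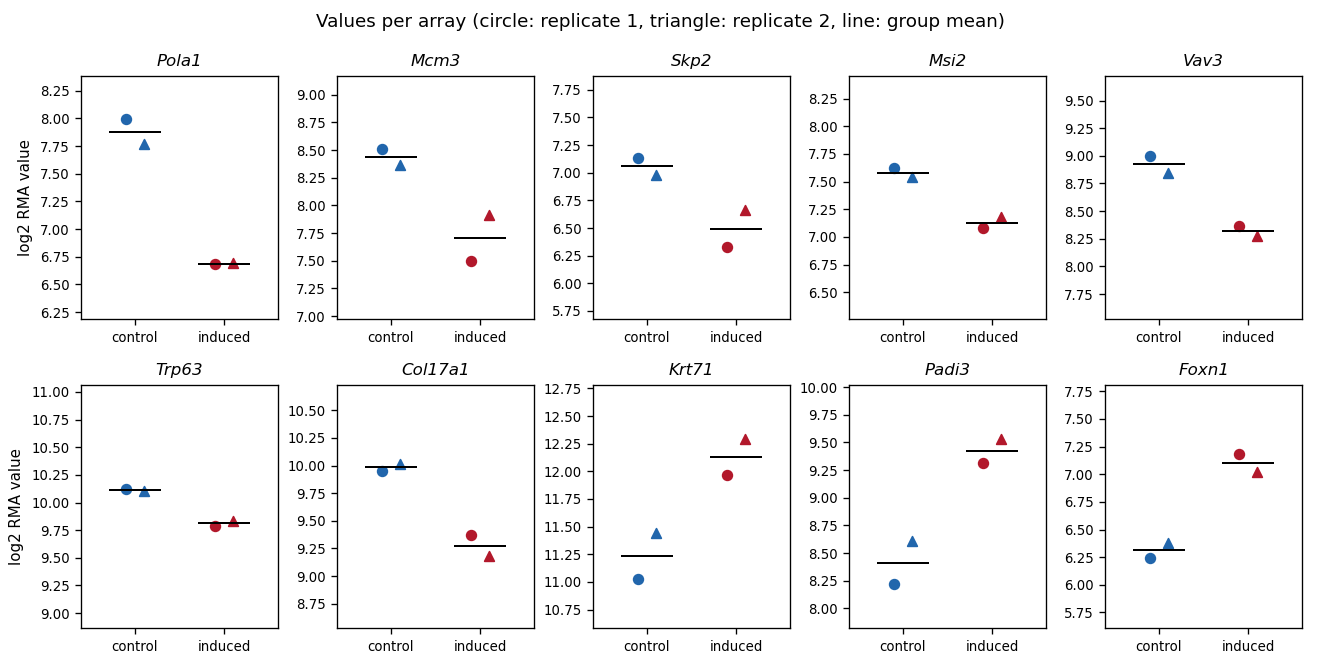
Log2 RMA value of 10 named genes on each of the 4 arrays (vertical axis, each panel spanning the same range in log2 units), with control arrays in blue and miR-203 induced arrays in red, circles for replicate 1, triangles for replicate 2 and a line at each group mean. Both induced arrays lie below both controls for Pola1, Mcm3, Skp2, Msi2, Vav3, Trp63 and Col17a1 and above them for Krt71, Padi3 and Foxn1, and no gene shown passed the adjusted threshold. Each gene is shown by its representative probe set, and 2 of the 3 other kept probe sets of Trp63 had the opposite sign.

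The genes taken as the study's own miR-203 targets, Skp2, Msi2 and Vav3, were all lower in both induced arrays than in both controls. Their naming as targets came from prior knowledge of the study and not from the sample labels. Vav3, a guanine nucleotide exchange factor, differed by -0.60 ± 0.11 (1.52-fold lower, adjusted p = 0.205). Skp2, the substrate-recognition subunit of an SCF ubiquitin ligase, differed by -0.57 ± 0.14 (1.48-fold lower, adjusted p = 0.308), with 1 of its 5 other kept probe sets at 0.00 ± 0.16. The RNA-binding protein gene Msi2 differed by -0.45 ± 0.10 (1.37-fold lower, adjusted p = 0.268). All 3 passed when adjusted over the list alone and 0 over all genes. The list passed camera (adjusted p = 1.69e-04; adjusted p = 0.682 with an estimated correlation). Whether the study chose these targets on these same arrays is not known here. Neither the count nor the test is therefore independent evidence of their direction.

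Targets of miR-203 from earlier publications were also lower as a group, 15 of 17 measured members having a lower mean in the induced arrays and 7 of those being separated, with a median of -0.13. The lowest were Lasp1, an actin-binding adaptor (-0.91 ± 0.17, 1.88-fold lower), the caveolar protein gene Cav1 (-0.84 ± 0.10, 1.79-fold lower) and Bmi1, a Polycomb group gene (-0.57 ± 0.12, 1.48-fold lower). These 3 passed when adjusted over the list alone. Trp63, which encodes the basal keratinocyte transcription factor p63, differed by -0.30 ± 0.09 (adjusted p = 0.385) in a probe set with a control mean of 10.1. Of its 3 other kept probe sets 2 had the opposite sign, at 0.46 ± 0.12 and 0.10 ± 0.14, so that its direction is uncertain. Those 2 were dimmer, with control means of 6.04 and 5.84. The list passed camera (adjusted p = 4.90e-04; adjusted p = 0.682 with an estimated correlation), and without induced replicate 1 its adjusted p was 0.0589, while the median was -0.29 without induced replicate 2.

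Basal keratinocyte genes were lower by a small amount, 13 of 17 measured members having a lower mean and 11 of those being separated, with a median of -0.13. The hemidesmosomal collagen gene Col17a1 differed by -0.71 ± 0.11 (1.63-fold lower) and was the 1 member past the threshold when adjusted over the list alone. Lama3, a laminin chain of the basement membrane, differed by -0.53 ± 0.12 and Krt15 by -0.33 ± 0.10. The basal keratins Krt5 and Krt14 differed by -0.17 ± 0.09 and -0.13 ± 0.09. The list passed camera (adjusted p = 0.00770; adjusted p = 0.682 with an estimated correlation), and not without control replicate 2 (adjusted p = 0.111). Neither differentiation list passed camera. The spinous list had a median of 0.00 over 13 members (adjusted p = 0.859), with Krt1 at -0.11 ± 0.10 and Krt10 at -0.07 ± 0.10. The list of granular layer and cornified envelope genes had a median of -0.02 over 25 members (adjusted p = 0.594), with loricrin (Lor) at 0.00 ± 0.09 and involucrin (Ivl) at -0.03 ± 0.09. Lor, Krt1, Krt10, Krt5 and Krt14 lay near the top of the measured range, at log2 values of 13.6 to 14.3. Within the second list Sprr1a differed by 0.50 ± 0.10 and Rptn by 0.47 ± 0.10.

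Hair follicle genes were higher as a group, 18 of 21 measured members having a higher mean in the induced arrays and 11 of those being separated, with a median of 0.31. Padi3, a peptidylarginine deiminase, was 2.01-fold higher (1.01 ± 0.16), the inner root sheath keratins Krt71 and Krt27 were 1.86-fold (0.90 ± 0.18) and 1.79-fold (0.84 ± 0.15) higher, and Foxn1, a transcription factor of hair shaft differentiation, was 1.73-fold higher (0.79 ± 0.11). When adjusted over the list alone 8 members were higher, against 0 over all genes. The list passed camera (adjusted p = 6.25e-07; adjusted p = 0.682 with an estimated correlation). Without induced replicate 2 the median was 0.07 and the adjusted p 0.0591, and without induced replicate 1, the array with Y-linked transcripts, the median was 0.66. Melanocyte markers were likewise higher without induced replicate 1 (median 0.45, adjusted p = 5.09e-07), though not with all arrays (median 0.18, adjusted p = 0.165).

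A further 3 lists passed camera with higher values in the induced arrays. The TGF-beta and BMP list had a median of 0.17 over 15 members, 13 of them higher, among them the pathway inhibitors Bambi (0.92 ± 0.16, 1.89-fold), Smad6 (0.67 ± 0.25) and Smad7 (0.35 ± 0.10) and the ligand gene Bmp4 (0.50 ± 0.22). With the mean of a gene's probe sets the median was 0.09. Bambi was the 1 member past the threshold when adjusted over the list alone, and the list's adjusted p was 0.00473 (adjusted p = 0.682 with an estimated correlation), becoming 0.108 without control replicate 2 and 0.156 (median 0.03) without induced replicate 2, while the median was 0.26 without induced replicate 1. The immediate early and dissociation stress list had a median of 0.12 over 18 members, 13 of them higher, with Klf6 at 0.33 ± 0.09 and Junb at 0.33 ± 0.10 and 0 members past the threshold over the list alone. Its adjusted p was 0.0205 (adjusted p = 0.883 with an estimated correlation), becoming 0.562 (median 0.02) without control replicate 2 and 0.428 without induced replicate 1, while the median was 0.21 without control replicate 1 and 0.19 without induced replicate 2. The miRNA machinery list had a median of 0.07 over 13 members, 10 of them higher, with Tnrc6c at 0.42 ± 0.10, Ago2 at 0.26 ± 0.10 and Dicer1 at 0.29 ± 0.14 and 0 members past the threshold over the list alone. Its adjusted p of 0.0431 (adjusted p = 0.682 with an estimated correlation) was lost when any array was left out (0.0617 to 0.181), the median reaching 0.11 without control replicate 1 and 0.13 without induced replicate 2, and when the values were quantile normalized again (0.0751), and the median was 0.11 with the filter at the 60th percentile.

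**Figure D2:**
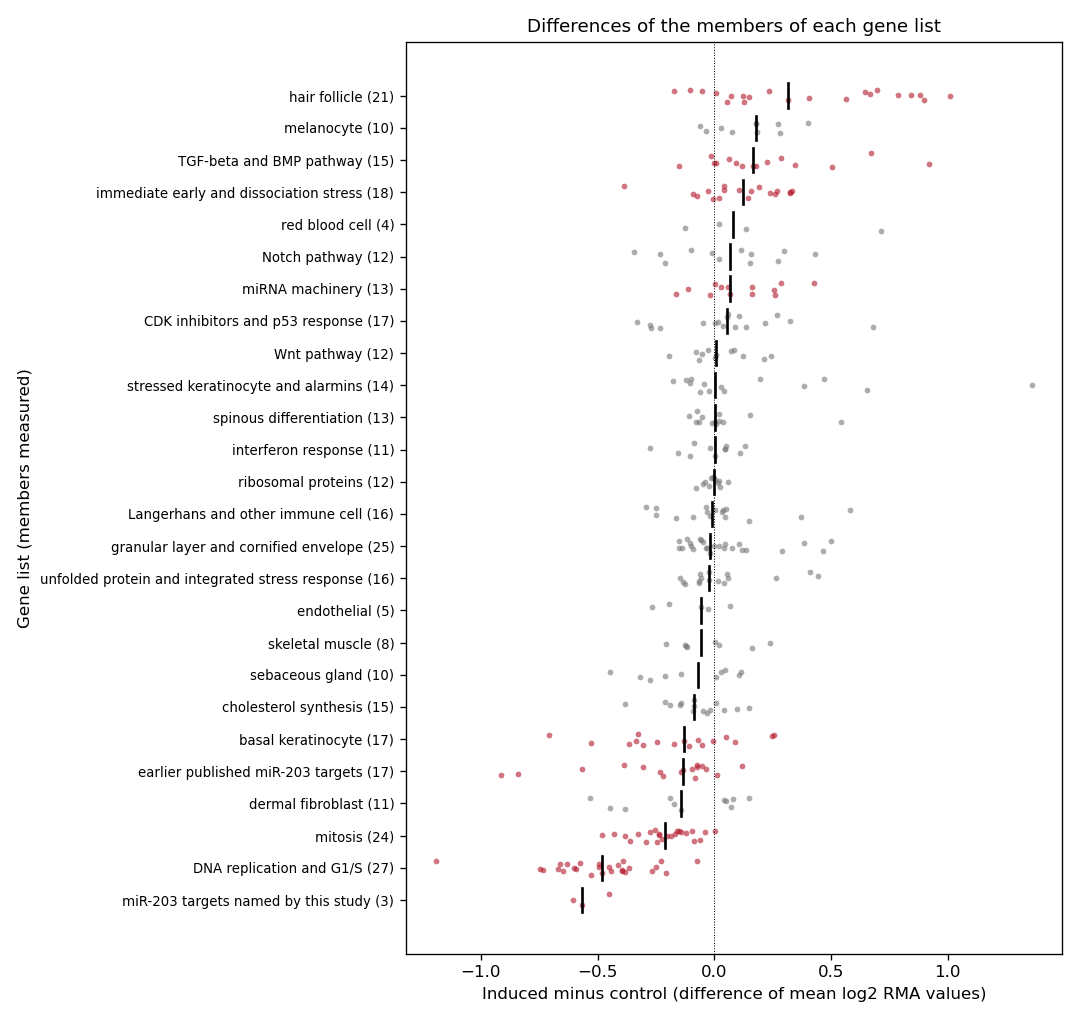
Difference between the induced and the control mean log2 RMA value (horizontal axis) of each measured member of the 26 gene lists tested (1 list per row, number of members in brackets, points spread vertically only to part them), with a black bar at the list median. Red marks the 9 lists past the camera threshold with the preset correlation and grey the others, and the medians run from -0.57 for the targets named by the study to 0.31 for the hair follicle list.

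In all, 9 of the 26 lists tested passed camera, 5 lower and 4 higher, and 5 lists passed without control replicate 2; none of the 9 did so with an estimated correlation, where the lowest adjusted p was 0.682. The estimated form took its correlation and its p-value from the 2 residual degrees of freedom, and the simulations did not include it. There 0 lists had an unadjusted p under 0.05, and DNA replication had an unadjusted p of 0.167 in camera. Not passing in that form therefore decides little by itself. Among the 9 lists its estimated correlations ran from -0.05 (basal keratinocyte) to 0.76 (DNA replication), with 0.74 for mitosis and 0.42 for hair follicle. Where members vary together by more than the preset 0.01, the p-values of the preset form are too small. limma's fry, which asks whether a list's members move on balance in one direction, called 0 lists (adjusted p = 0.465 for DNA replication). Its mixed form, which asks whether they change in either direction, called 4, namely the basal keratinocyte, granular and stressed keratinocyte lists (adjusted p = 0.0278 each) and miRNA machinery (0.0467), and neither the DNA replication, mitosis nor hair follicle list (0.207, 0.433 and 0.170). Splits that joined a control with an induced array gave 7 and 3 lists past the camera threshold, so that passing it does not by itself separate the induced from the control arrays. The other 17 lists did not pass camera. Markers of other cell types had medians of 0.18 for melanocytes (adjusted p = 0.165), 0.08 for red blood cells (0.202), -0.01 for Langerhans and other immune cells (0.859), -0.06 for endothelium (0.378), -0.06 for skeletal muscle (0.859), -0.07 for sebaceous gland (0.327) and -0.14 for dermal fibroblasts (0.327). The melanocyte list passed without induced replicate 1 (median 0.45), as did cholesterol synthesis (-0.15) and Wnt (0.12), and without induced replicate 2 the lists of dermal fibroblasts (-0.39), sebaceous gland (-0.16) and stressed keratinocytes (0.03) passed. Pathway lists had medians of 0.07 for Notch (0.640), 0.01 for Wnt (0.700), -0.09 for cholesterol synthesis (0.249), -0.02 for the unfolded protein and integrated stress response (0.640), 0.00 for interferon response (0.859) and -0.00 for ribosomal proteins (0.873). The stressed keratinocyte list had a median of 0.00 (0.238), although Krt6b (1.36 ± 0.36), Krt6a (0.66 ± 0.11) and Sprr1b (0.38 ± 0.10) passed when adjusted over the list alone. Slc4a1 (0.71 ± 0.11), the anion exchanger of red cells, passed likewise. The median, the mean and the test differed in sign for the granular, unfolded protein, interferon and immune lists, none of which passed camera.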

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

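All tests in this part were chosen after the results were seen.

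Transcripts of the Y chromosome appeared in induced replicate 1 above their level in both control arrays, in probe sets that no tested list used. The log2 difference from the higher control was 6.56 for Eif2s3y, 4.49 for Kdm5d and 3.78 for Uty; the control values, 2.47 to 3.17, lay below the filter level of 4.17, so these sizes are at best lower bounds. These are the probe sets with the highest signal for each gene. On the same scale the other probe set of Eif2s3y showed no rise (0.00), nor did the other pair for Kdm5d (0.12 and -0.20), while the other 3 of Uty were higher by 1.23 to 2.05. Xist was lower there than on every other array, by -4.71 from the nearest. Induced replicate 1 thus had the pattern of male cells, and the other arrays that of female cells. The sample labels used here do not give the sex. No explanation was tested on other values, and with 1 such array a difference in sex cannot be separated from the other differences of that replicate.

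The DNA replication list was lower in induced replicate 2 as well, at -0.32 from the control mean, against 0.17 between the controls. Relative to all genes, the list mean was 1.19 and 1.01 in the controls and 0.44 and 0.78 in the induced arrays. The induced arrays thus differed from each other by about as much as replicate 2 did from the control mean. How far the list rests on induced replicate 1 is therefore uncertain. A lower share of cycling cells may account for the lower list and stays open. The mitosis list differed from the replication list by 0.28, close to the largest difference between replicate arrays in the same contrast (0.26), so a general loss of cycling cells and a loss restricted to DNA replication genes cannot be told apart. The comparison of the groups bears on an effect of induction on these genes, and the list passed camera only with the preset correlation. That comparison cannot tell an effect of miR-203 from one of the activator. Whether miR-203 acts on these genes directly is untested, because no seed matches were examined.

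The median of the hair follicle list rested mostly on induced replicate 2. There the median of the 21 measured members was 0.66 from the control mean and 20 were higher, against 0.067 and 13 in induced replicate 1. A larger share of hair follicle cells may account for it and stays open, since the median of induced replicate 1 lay within the 0.087 by which the controls differed. Earlier versions of this check, also made after the values were seen, gave different answers, so its outcome depends on the version kept. Members went both ways in induced replicate 1, with Shh at -0.87, Gli1 at -0.75 and Lhx2 at -0.54 but Padi3 at 0.90 and Foxn1 at 0.87, named after their values were seen. The controls differed in the same directions, by -0.54, -0.36, -0.27, 0.39 and 0.14. Keratin-associated protein genes of the hair shaft, outside the list and picked after their values were seen, were higher in both induced arrays. Their median over 37 genes was 1.09 from the control mean in induced replicate 1 and 0.73 in induced replicate 2. Control replicate 2 lay 0.34 above control replicate 1 for them. The higher values of this family were thus not confined to 1 array. Because the family was picked on values from both induced arrays, this gives no independent support for the hair follicle list. Animals at different stages of hair follicle growth stay possible too. The list median differed by 0.087 between the controls, against 0.31 between the groups. That small median hides members that differed between the controls from -0.54 (Shh) to 1.14 (Krt35), 14 of the 21 being higher in control replicate 2.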

How the results depend on the processing

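The settings added after seeing the data were the crossed pairing, eBayes with trend but not robust, adjustment over representative probe sets only, and leaving out arrays for the separated genes. No result past its threshold reversed direction. The count of 0 genes and 0 probe sets past the threshold held under each other filter, normalization, threshold and rule for several probe sets, while eBayes with trend and robust gave 126 probe sets (68 higher, 58 lower) and 81 genes (54 and 27), and with trend alone 78 probe sets (44 and 34) and 50 genes (33 and 17); the cause was not tested. The same trend and robust test called 0 probe sets in either other split of the arrays, and there are too few splits for a share under 0.05. Leaving out arrays gave 0 to 6 probe sets (0 to 3 higher, 0 to 3 lower) and 0 to 2 genes (0 to 1 each way). The 6, without induced replicate 2, were 3 probe sets of Xist, 1 of Eif2s3y and 2 unnamed ones. The 9 lists became 0 with an estimated correlation and 0 with fry, and 5 to 9 when arrays were left out, with 5 without control replicate 2. The other splits gave 7 and 3 lists, and that with 3 included DNA replication (median 0.27). The split with 7 included hair follicle (-0.27), mitosis (-0.18, adjusted p = 2.81e-07) and immediate early genes (0.13, adjusted p = 1.94e-04), the last 2 with a smaller adjusted p than between the real groups (1.75e-05 and 0.0205). The 236 separated genes (135 higher, 101 lower) became 49 at 2-fold (44 and 5, the 5 lower being Slc18b1, Pola1, Hells, Atf2 and Tsen15, named after their values were seen), and 231 to 364 when arrays were left out (143 to 222 higher, 88 to 218 lower), where a lone array separates from a pair more easily by construction. The difference of replicate 1 minus 2 correlated at -0.100 between the groups, and the numbers were not taken to pair the arrays. With the replicate number as a block 0 probe sets, 0 genes and 9 lists passed, the same calls as without it, and with crossed pairing 0, 0 and 8. Among values of lists, 293 were the same, 32 lost the threshold, 6 gained it and 31 changed sign without passing; among values of named genes 1356 were the same, 28 gained the threshold and 17 changed sign without passing. The seed-site test and its alternatives were not run. Without the filter, probe sets under its level of 4.17 were tested too, and 0 passed.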

Other observations

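The keratin-associated protein family and the 4 genes below were picked after their values were seen, and the variance prior with trend and robust was chosen as an alternative beforehand.

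Keratin-associated protein genes, which encode matrix proteins of the hair shaft and were in none of the gene lists, had higher values in the induced arrays. All 37 measured members had a higher mean there, with a median difference of 0.92 and a range of 0.01 to 1.36. They made up 33 of the 135 genes that were separated and at least 1.5-fold higher, or 24.4%. Members of the family are similar in sequence. Among the 34 represented by probe sets of the plain kind, named at array design as meant for a single gene, 31 were separated and at least 1.5-fold higher. Cross-hybridisation within the family was not tested, so the members may not be separate measurements. The median was 1.09 above the control mean in induced replicate 1 and 0.73 in induced replicate 2, while control replicate 2 lay 0.34 above control replicate 1. With the trend and robust prior in limma 17 members passed the adjusted threshold, and with the main prior 0 did.

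Krt26 (1.21), Krt72 (1.13) and Krt32 (0.84), hair follicle keratins outside the fixed lists, were higher with the trend and robust prior, while Sostdc1, an inhibitor of BMP and Wnt signalling, was lower (-0.83). With the main prior none of the 4 passed.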
